A study of Macaca mulatta with 20 samples.

How the data were processed

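RNA-seq libraries were made from liver biopsies of 10 rhesus monkeys (Macaca mulatta), 5 on a control diet (Control) and 5 under caloric restriction (CR), with 1 biopsy per animal at enrolment (year 0) and 1 after 2 years. Diet and year of each library came from the labels, and the animal number in the labels' titles tied the biopsies of an animal to each other. Total RNA was extracted from the tissue and turned into TruSeq libraries that were sequenced paired-end on an Illumina instrument, per the labels' protocols. The 20 libraries form 4 groups of 5.

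The authors deposited expected counts per gene and per transcript, which are estimated from the aligned reads without any normalization and hold fractions of reads because reads shared between features were divided: 4.37% of the gene values and 17.5% of the transcript values were not whole. The authors also deposited TPM (estimated transcripts per total of transcripts, scaled to a fixed sum per library) per gene and per transcript. STAR, RSEM and DESeq2 and the genome build Mmul_8.0.1 (rheMac8) are named in the submitters' processing notes, without versions and without the role of each. The gene annotation, read trimming and strand setting are not given in the sources used here. The tables cover 18288 genes and 22181 transcripts, and 2204 genes (12.1%) had more than 1 transcript. Features carry symbols in the tables, and 15272 of them matched a symbol in a list of gene names. A further table from the authors gives the mean of normalized counts, log2 fold changes, p-values and adjusted p-values, per the file headers, for 3071 genes without naming the comparison or the filter. FPKM tables of the same libraries were not used here.

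Estimated counts were rounded to whole numbers, since the count models need them. Library totals ran from 15421789 to 31440640 counts, with 20883559 in the second shallowest library. No pair of libraries held identical values, and correlations between libraries of log2 CPM (counts scaled to the library total, prior count 1) ran from 0.830 to 0.986. Genes were kept by filterByExpr of edgeR 4.0.16 (R 4.3.3), which left 13730 genes over 20 libraries, 13345 at year 2 and 13244 at year 0. Counts were scaled by TMM and tested with edgeR's quasi-likelihood F test (robust), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Other scaling by relative log expression moved the median log2 change of all genes by at most 0.016 in any comparison.

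The change over 2 years in CR, the change in Control and their difference (diet by year interaction) came from 1 fit of all 20 libraries with a term per animal (the animal block) and a year 2 term per diet. CR was compared with Control at year 0 and at year 2 in fits of the 10 libraries of that year. The pairing comes from the labels: both biopsies carry the same animal number. The correlation of an animal's year 0 and year 2 deviations from the group means was 0.16 in animal 001, 0.12 in 004, 0.08 in 011, 0.07 in 012 and 0.01 in 008. It was -0.25 in 005, -0.22 in 009, -0.14 in 007, -0.03 in 010 and -0.02 in 006. The own value exceeded the highest correlation with another animal of the same diet only in 001 and 012. These values thus show little likeness between the biopsies of an animal. No block is named in the submitters' processing notes. The block was kept because the same animals were sampled at both times, and the fit without it is given with the alternatives.

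Transcript usage, the share of a gene's RNA given by each transcript, was tested with diffSpliceDGE of edgeR (Simes p per gene) on rounded transcript counts with the same designs. Transcripts needed at least 10 counts in at least 5 libraries and a mean share of at least 5% of their gene, which left 1185 genes with 2687 transcripts. Transcript names are those of the authors' table, and their exon structure was not used here.

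The comparisons, alternatives, gene lists and rule for named genes were set before the data were examined, with the exceptions stated here. The 41 gene lists cover RNA processing (spliceosome components, splicing regulators, mRNA 3' end processing, RNA decay), fatty acid oxidation, ketone bodies, fatty acid and triglyceride synthesis, cholesterol, bile acids, gluconeogenesis, glycolysis, branched-chain amino acids, urea cycle and amino acids, one-carbon metabolism, TCA cycle, oxidative phosphorylation, mitochondrial and cytosolic ribosome, proteasome, cytochrome P450 and drug metabolism, insulin and IGF, circadian clock, autophagy, NRF2, unfolded protein response, heat shock, acute phase, interferon, immediate-early genes, cell cycle and hepatocyte secretory genes. They also cover markers of stellate cells, macrophages, lymphocytes (T, NK and B cells), neutrophils, endothelial cells, cholangiocytes, red blood cells, skeletal muscle, adipocytes, and kidney, pancreas and gut. Lists with at least 5 measured genes were tested with camera of limma 3.58.1, with the correlation between genes preset to 0.01 and adjustment over the 40 lists of a comparison. Camera with an estimated correlation, and fry, were alternatives. A list score is the mean log2 CPM of the list's genes in a library, and exact tests of scores (all sign flips of 5 animals, all splits of 10 animals into 5 and 5) were added after the gene fits had been seen. Such tests cannot go below 0.0625 within a diet or 0.00794 between diets.

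Named genes are, per comparison and direction, the 8 with the largest absolute log2 fold change among those with an adjusted p under 0.05, a mean log2 CPM of at least 1 and the same sign in every animal of the diet (between diets, no overlap of the 5 values of each). Where fewer than 4 qualified, genes with the smallest p filled up to 4 and are said not to meet the rule. A panel of 24 metabolic, splicing and ageing genes was named in the CR change and the interaction, and of each called list the 3 members with the smallest p could be named. Some genes that these rules pick are not reported here. For transcript usage the rule takes the 6 genes with the largest change in share among those called.

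Alternatives were other size factors, no filter on low counts, DESeq2 1.42.0 (Wald test), limma on log2(TPM + 1) of genes with a mean TPM of at least 1, no animal block, the spread of 1 diet alone or of all 20 libraries, leaving out each animal, other tests and a share of at least 10% for transcript usage, and other gene sets for the correlation of the diets' changes. Leaving out animals 001 and 009 together was added after their year 2 libraries were seen to stand apart. DESeq2 of the interaction was also compared with the authors' table.

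Counts were simulated with the real means and depths, the spread of the fit of all 20 libraries and an added random effect per animal. On these the gene test recovered 90.9% of 4-fold and 28.4% of 2-fold changes in the CR change. It recovered 92.4% and 19.4% in the Control change, and 59.1% and 1.49% in the interaction. The values were 84.8% and 17.9% at year 2 and 89.4% and 20.9% at year 0, and at 1.5-fold 0% except for 1.49% at year 0. The common coefficient of variation was 0.345 in the fit of all 20 libraries, 0.415 in that of year 2 and 0.254 in that of year 0. Recovery at year 2 and year 0 was thus not simulated at the spread of those fits. A simulated list shifted by 0.5 on the log2 scale had an adjusted p of 5.47e-18, and 0 other lists were called. Genes were simulated independently of each other, so that this does not test whether camera's preset correlation suits the real lists. The transcript test recovered 5%, 7%, 1% and 10% of genes in which 50% of a transcript's reads were moved (CR change, Control change, interaction, year 2) and 72%, 68%, 48% and 67% when 95% were moved, at a median transcript coefficient of variation of 0.578.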

Results

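Gene expression was measured in liver biopsies of 10 rhesus monkeys, 5 fed a control diet (Control, animals 001, 005, 006, 009 and 010) and 5 under caloric restriction (CR, animals 004, 007, 008, 011 and 012). Each animal gave 1 biopsy at enrolment (year 0) and 1 after 2 years on its diet, so that there were 5 libraries in each of 4 groups. Library totals were 15421789 counts in Control animal 009 at year 2 and between 20883559 and 31440640 in the other 19. Albumin RNA, the most abundant hepatocyte product, took 5.42% of the counts in Control 009 at year 2 and 8.57% in Control 001 at year 2, against 10.6% to 15.8% elsewhere. Both libraries also stood apart on the first principal component (27.3% of the variance), at 129.65 and 67.4. Their median correlation with the other libraries was 0.851 and 0.898, against at least 0.954. The 10 most abundant genes took 12.6% of the counts in Control 009 at year 2 and 30.5% in Control 001 at year 2, and their TMM factors were 1.66 and 0.763.

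**Figure D1:**
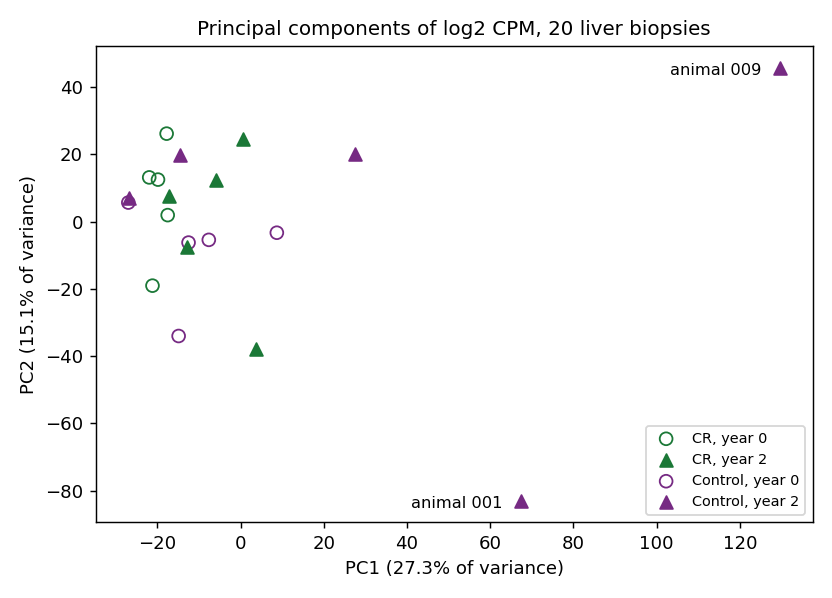
Each point is 1 library on the first and second principal components of log2 CPM (27.3% and 15.1% of the variance), coloured by diet and shaped by year. The year 2 libraries of Control animals 009 and 001 lie at 129.65 and 67.4 on the first component.

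The animals were compared at year 0, before the diets started, to measure differences between the arms that were there at enrolment. By camera at its preset correlation, macrophage genes were higher in the animals assigned to CR, and genes of mitochondrial respiration, ribosomes and hepatocyte secretion were lower. Of the 40 lists 0 were called at year 0 with an estimated correlation (adjusted p of at least 0.283), and fry called 9, without the cytosolic ribosome. CLEC7A, a receptor of myeloid cells for fungal glucans, was higher by 1.80 ± 0.26 on the log2 scale (SE, n = 5 per group, adjusted p = 0.036), at 4.36 ± 1.08 CPM against 1.25 ± 0.43 (SD). CD180, a Toll-like receptor relative of B cells and macrophages, was higher by 1.47 ± 0.15 (adjusted p = 0.0048), at 8.27 ± 1.11 CPM against 2.99 ± 0.48. MPEG1, a pore-forming protein of macrophages, was higher by 1.62 ± 0.28 (adjusted p = 0.050), and CD4 by 0.81 ± 0.12 (adjusted p = 0.036). APOL6 (1.58 ± 0.25), CECR1 (1.58 ± 0.26), IGSF6 (1.44 ± 0.23), SEL1L3 (1.40 ± 0.21) and the class II antigen presentation gene MAMU-DQB1 (1.44 ± 0.21) were also higher, with adjusted p from 0.037 to 0.044. Lower in CR were GSTA5, a glutathione transferase (-0.79 ± 0.13; 305 ± 25.8 CPM against 527 ± 88.9), ATP13A4 (-0.66 ± 0.11), AASDH (-0.62 ± 0.10) and ASGR2, a subunit of the hepatocyte asialoglycoprotein receptor (-0.57 ± 0.09), with adjusted p from 0.044 to 0.048. MHC and GSTA genes belong to families of near-identical copies, so that their estimated counts are uncertain. In all, edgeR called 32 of 13244 genes, 28 higher and 4 lower in CR. The 5 values of CR did not overlap with those of Control in 662 genes (5.00%, against 0.794% by chance). DESeq2 called 780 genes, limma on log2(TPM + 1) 361, edgeR without a filter 13 and edgeR over all 20 libraries 0. Each of the 32 genes kept its direction wherever it was tested. Leaving out animal 001 gave 340 calls, 004 gave 93 and 009 gave 44. Leaving out 011 gave 4 and leaving out 005, 006, 007, 008, 010 or 012 gave 3 each.

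Among the gene lists, the macrophage markers were higher in CR at year 0 in 23 of 25 genes, with a median of 0.59 (camera adjusted p = 1.01e-17, adjusted p = 0.283 with an estimated correlation). MS4A7 (0.84 ± 0.15), LAPTM5 (0.79 ± 0.14) and CD5L, a scavenger protein of Kupffer cells (0.97 ± 0.18), had the smallest p, and 18 members passed when adjusted over the list alone. Oxidative phosphorylation genes were lower in 74 of 76, with a median of -0.28 (adjusted p = 3.61e-16; 0.342 as adjusted p with an estimated correlation) and 31 called when adjusted over the list alone, among them the ATP synthase subunit ATP5H (-0.43 ± 0.09). Genes of the mitochondrial ribosome had a median of -0.23 (66 of 72 lower, 16 adjusted over the list alone) and those of the cytosolic ribosome -0.23 (80 of 80 lower, 0 adjusted over the list alone), each with an adjusted p of 1.34e-11. With an estimated correlation the adjusted p was 0.283 for the mitochondrial and 0.444 for the cytosolic ribosome. Spliceosome components, the machinery that removes introns, were lower in 87 of 97, with a median of -0.17 (adjusted p = 8.57e-08, adjusted p = 0.342 with an estimated correlation) and 0 members adjusted over the list alone. PRPF18 (-0.40 ± 0.09) and BCAS2 (-0.52 ± 0.13) were among its members of smallest p. Splicing regulators had a median of -0.10 (66 of 86 lower, adjusted p = 0.00179, adjusted p = 0.444 with an estimated correlation), and adjusted over the list alone CELF2 (1.10 ± 0.22) was higher and TIA1 (-0.39 ± 0.09) lower in CR. Cholesterol synthesis genes had a median of -0.43 (24 of 27 lower, adjusted p = 8.57e-08, adjusted p = 0.342 with an estimated correlation; 4 adjusted over the list alone), with TM7SF2, a sterol reductase, at -0.57 ± 0.11. Proteasome genes stood at -0.21 (10 adjusted over the list alone) and hepatocyte secretory genes at -0.22 (4 adjusted over the list alone), with adjusted p of 1.01e-06 and 7.73e-06. Their adjusted p with an estimated correlation was 0.357 and 0.283.

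Interferon response genes, which cells switch on against viruses, were higher in CR at year 0, with a median of 0.51 (38 of 44, adjusted p = 1.38e-07; 3 adjusted over the list alone), GBP1 among them at 1.40 ± 0.34. T, NK and B lymphocyte markers stood at 0.55 (adjusted p = 2.57e-06; 2 adjusted over the list alone), endothelial markers at 0.34 (8.2e-05), neutrophil markers at 0.48 (0.00225; 3) and cell cycle genes at 0.30 (0.0424). With an estimated correlation the adjusted p of these 5 lists ran from 0.393 to 0.59. Lower at year 0 were urea cycle genes (-0.26), stellate cell markers (-0.18; 3 adjusted over the list alone), red blood cell markers (-0.98; 2), fatty acid oxidation (-0.14), cytochrome P450 and drug metabolism (-0.11), acute phase (-0.11) and branched-chain amino acid catabolism (-0.12). Camera's adjusted p of these 7 lists ran from 0.000551 to 0.0388, and with an estimated correlation from 0.283 to 0.522. In all 21 lists were called, 6 higher and 15 lower. With an estimated correlation 0 were called, and 9 were by fry, which tests whether a list's genes move on balance 1 way. Camera and fry shared 8 of these: macrophage, oxidative phosphorylation, mitochondrial ribosome, cholesterol, spliceosome, proteasome, hepatocyte secretory and cytochrome P450 genes, with fry adjusted p between 0.00473 and 0.0483. Of the 21 lists 15 were called without each animal in turn and without 001 and 009 together. The interferon median was 0.24 and the lymphocyte median 0.25 without animal 004, the neutrophil median 0.95 without 009 and the endothelial median 0.19 without 001. Without 005 the red blood cell median was -0.64, the cytosolic ribosome median -0.13 and that of splicing regulators -0.064. The remaining 6 calls were lost without single animals: cell cycle without 001 (0.25), 004 (0.24), 005 (0.25), 006 (0.23), 008 (0.26) or 011 (0.30). Branched-chain amino acids were lost without 004 (-0.13), 006 (-0.14), 007 (-0.095), 008 (-0.11), 009 (-0.12) or 010 (-0.15). Fatty acid oxidation was lost without 004 (-0.13), 006 (-0.083) or 009 (-0.084). Acute phase was lost without 006 (-0.025) or 008 (-0.086), stellate markers without 004 (-0.11) or 010 (-0.12), and cytochrome P450 without 007 (-0.12). The calls of cytochrome P450 (-0.11, adjusted p = 0.12), branched-chain (-0.15; 0.126) and cell cycle genes (0.28; 0.277) were also lost without 001 and 009 together, and insulin and IGF genes were called there (-0.15; 0.0245). Called and larger were cell cycle genes without 007 (0.46) or 010 (0.57), cytochrome P450 without 005 (-0.17), acute phase without 001 (-0.17) or without 001 and 009 (-0.19), and cytosolic ribosome without both (-0.35).

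**Figure D2:**
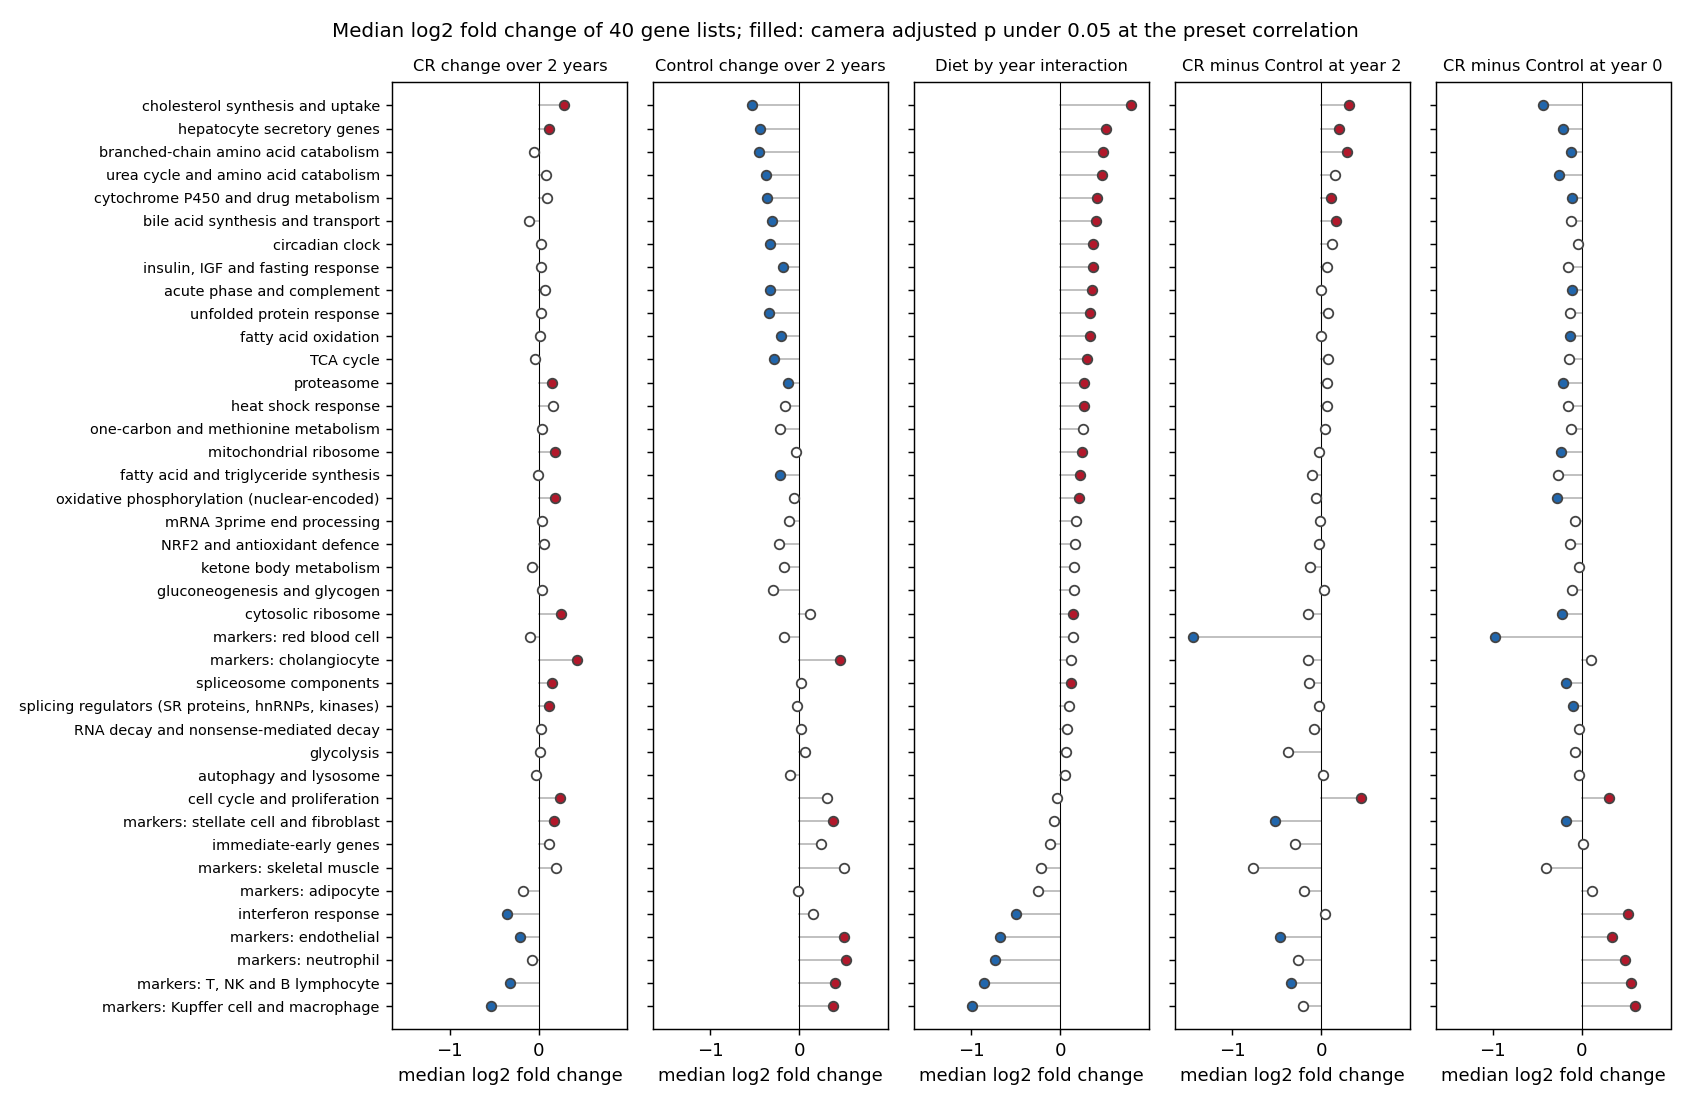
Median log2 change of each gene list (horizontal axis) in the 5 comparisons, with filled points where camera called the list, red for higher and blue for lower. At year 0 the macrophage list stands at 0.59 and the oxidative phosphorylation list at -0.28.

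The change over 2 years in the CR animals was measured next. It mixes the diet with 2 years of time and a start that may have differed between the arms, and does not isolate the diet. By camera at its preset correlation, lists of protein synthesis, respiration and splicing were higher at year 2 by small amounts and macrophage markers lower, while 0 lists were called with an estimated correlation (adjusted p from 0.726 to 0.959) and 0 by fry. All 80 genes of the cytosolic ribosome, which translates mRNA, were higher at year 2, with a median of 0.25 (adjusted p = 3.33e-13), RPL12 at 0.52 ± 0.24 and RPL39 at 0.41 ± 0.18 (SE, n = 5 animals). Mitochondrial ribosome genes rose in median by 0.18 (64 of 72 higher, adjusted p = 2.34e-07), with MRPS31 at 0.71 ± 0.28. Oxidative phosphorylation genes rose by 0.19 (69 of 76, adjusted p = 1.08e-06), with NDUFA12 at 0.27 ± 0.16. Proteasome genes, which degrade proteins, rose by 0.15 (34 of 40, adjusted p = 0.000578). These 4 lists had an adjusted p of 0.837 with an estimated correlation. Spliceosome components rose in median by 0.15 (83 of 97 higher, adjusted p = 3.35e-06) and splicing regulators by 0.11 (66 of 87, adjusted p = 0.00122), both with an adjusted p of 0.726 with an estimated correlation. Members with the smallest p were MAGOHB, a part of the exon junction complex (0.48 ± 0.18), CWC15 (0.36 ± 0.15), the kinase CLK4, which phosphorylates splicing factors (0.49 ± 0.23), and the splicing factors SRSF3 (0.36 ± 0.18) and TRA2B (0.32 ± 0.16), none of them called on its own. Of the other RNA lists, 3' end processing (median 0.04, adjusted p = 0.392) and RNA decay (median 0.02, adjusted p = 0.428) were not called. The spliceosome score was higher at year 2 in 5 of 5 CR animals, by 0.14 ± 0.11 (SD), at the smallest exact p that 5 animals allow (0.0625; adjusted over the lists 0.512).

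Macrophage markers fell by 0.53 in median in CR (23 of 25 lower, adjusted p = 1.59e-10, adjusted p = 0.726 with an estimated correlation), with the integrin ITGAM at -1.28 ± 0.46, CD5L at -0.88 ± 0.41 and the mannose receptor MRC1 at -0.87 ± 0.41. The macrophage score went from 5.57 ± 0.09 to 5.02 ± 0.71 (SD, n = 5) and was lower in 5 of 5 animals (exact p = 0.0625). Interferon response genes had a median of -0.36 (34 of 44 lower, adjusted p = 0.000161), with IFIT1 at -0.65 ± 0.24, lymphocyte markers -0.33 (22 of 28; 0.00143), with CD4 at -0.82 ± 0.32, and endothelial markers -0.20 (0.00557). These 3 lists had an adjusted p of 0.837 with an estimated correlation. Cholangiocyte markers, which bile duct cells express, rose by 0.43 (18 of 20, adjusted p = 8.69e-09, adjusted p = 0.726 with an estimated correlation), with osteopontin SPP1 at 1.00 ± 0.27. Cholesterol synthesis genes rose by 0.28 (21 of 27, adjusted p = 0.000517), with HMGCS1, which makes the precursor of mevalonate, at 0.79 ± 0.23 and squalene epoxidase SQLE at 0.67 ± 0.35. Cell cycle genes stood at 0.24 (adjusted p = 0.0022) and stellate cell markers at 0.18 (0.00336). The adjusted p of these 3 lists was 0.837 with an estimated correlation, and hepatocyte secretory genes (0.11, adjusted p = 0.0253) had 0.959. In all 15 of 40 lists were called in CR, 11 higher and 4 lower. Neither an estimated correlation nor fry gave a call (0 and 0), and 1 gene in the 40 lists passed when adjusted over the list alone, LPL among the adipocyte markers.

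Of the 15 lists 10 were called without each animal in turn. Leaving out a Control animal reaches the CR change only through the shared spread, scaling and filter, so that those leave-outs test little. Without animal 004 the interferon median was -0.025 (adjusted p = 0.771), the lymphocyte median -0.0039 (0.904), the endothelial median -0.096 (0.384) and the hepatocyte secretory median 0.10 (0.255). Without animal 007 the endothelial (-0.050), hepatocyte secretory (0.070) and cell cycle (0.055) calls were lost, and without 012 that of the cell cycle (0.10). The same lists were called and larger without other animals: interferon (-0.54) and endothelial genes (-0.37) without 011, endothelial without 012 (-0.35), and cell cycle without 004 (0.49) or 011 (0.43). Among the 10 kept, the macrophage median was -0.31, the cholangiocyte median 0.21 and the cholesterol median 0.16 without 004. Without 007 the cholangiocyte median was 0.69, the stellate median 0.28 and the cholesterol median 0.17. Without 012 the median was 0.12 for the mitochondrial ribosome and 0.072 for splicing regulators. Without the Control animals 001 and 009 together the 15 lists were called, and heat shock genes as well (0.15, adjusted p = 0.0406). Since the CR animals stayed the same, this is no test of the CR change.

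Among lists not called in CR, fatty acid oxidation had a median of 0.01, ketone bodies -0.07, fatty acid and triglyceride synthesis -0.01, bile acids -0.11, and gluconeogenesis 0.04. Glycolysis had a median of 0.02, branched-chain amino acids -0.05, urea cycle 0.09, one-carbon metabolism 0.04 and the TCA cycle -0.04. Drug metabolism stood at 0.09, insulin and IGF at 0.02, the circadian clock at 0.03, autophagy at -0.02, NRF2 at 0.06, the unfolded protein response at 0.02, heat shock at 0.16, acute phase at 0.07 and immediate-early genes at 0.12. Neutrophil markers stood at -0.08, red blood cell markers at -0.10, skeletal muscle markers at 0.20 and adipocyte markers at -0.17. Adjusted p of these 23 and the RNA lists not called ran from 0.0575 to 0.993. The list of kidney, pancreas and gut held 4 measured genes and was not tested by camera, and its score changed by -0.56 ± 0.77 (SD, n = 5) in CR.

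No single gene passed the threshold in the CR change: edgeR called 0 of 13730. At an unadjusted p under 0.05 were 397 genes (156 higher, 241 lower, against 686 by chance). These p-values rest on a spread shared with the Control libraries. With the spread of the CR libraries alone edgeR also called 0 genes. Since 397 is below the number by chance, the test may have been conservative for CR. The 0 calls thus do not show that genes stayed unchanged in CR. DESeq2 called 18 (7 higher, 11 lower) and limma on log2(TPM + 1) 0. The smallest p, none meeting the rule for named genes, belonged to MMP27 (7.16 ± 1.08, adjusted p = 0.261), a value that rests on a mean of 0.0366 CPM at year 0 and gives no size. Next came the transcription factor gene IRX3 (2.84 ± 0.48, adjusted p = 0.428), GALNTL2 (0.84 ± 0.18) and ITM2A (1.21 ± 0.28). Lowest were DNAH10, a dynein chain of cilia (-4.37 ± 0.84), CDX2 (-2.19 ± 0.43), WDR93 (-1.83 ± 0.38) and BST1 (-1.22 ± 0.26), with adjusted p from 0.708 to 0.781. Each of these 8 had the same sign in 5 of 5 CR animals, as did 1677 genes (12.2%, against 6.25% by chance). Of the panel, fatty acid synthase FASN stood at 0.60 ± 0.52, SREBF1 at -0.31 ± 0.41, ACACA at -0.07 ± 0.26, and SCD at 0.02 ± 0.54. PPARA, the regulator of fat oxidation, stood at -0.44 ± 0.27, PPARGC1A at -0.22 ± 0.52, CPT1A at -0.25 ± 0.78, and PDK4 at 0.31 ± 0.28. The growth factor IGF1 (0.08 ± 0.30), IGFBP1 (0.14 ± 0.49), FGF21 (-0.13 ± 0.89), CYP7A1 (-0.75 ± 1.39), PCK1 (-0.22 ± 0.39) and G6PC (-0.35 ± 0.42) were not called. Nor were SRSF1 (0.11 ± 0.21), HNRNPA1 (0.24 ± 0.18), SIRT1 (0.14 ± 0.25), FOXO1 (0.19 ± 0.23), TXNIP (-0.01 ± 0.34) and CRP (0.09 ± 0.60), and each panel gene named here had an adjusted p of 0.999.

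In the Control animals, the background for the CR change, camera at its preset correlation called 14 lists lower over 2 years, several of them of hepatocyte metabolism. With an estimated correlation 0 lists were called (adjusted p from 0.555 to 0.806) and by fry 0, and gluconeogenesis, glycolysis, one-carbon metabolism and ketone bodies were not called. Genes of branched-chain amino acid breakdown fell in median by 0.45 (27 of 29 lower, adjusted p = 4.17e-07), with 7 called when adjusted over the list alone. DBT (-0.90 ± 0.22; SE, n = 5 animals) and BCKDHB (-0.93 ± 0.26), subunits of the complex that commits these amino acids to oxidation, and its phosphatase PPM1K (-1.10 ± 0.31) had the smallest p. Cholesterol synthesis genes fell by 0.54 (24 of 27, adjusted p = 8.62e-07; 2 adjusted over the list alone), with DHCR7, the last enzyme of synthesis, at -1.35 ± 0.36, LSS at -1.03 ± 0.28 and the regulator SREBF2 at -1.04 ± 0.31. Urea cycle and amino acid genes fell by 0.37 (34 of 42, adjusted p = 0.000244), with the glycine-cleaving GLDC at -1.35 ± 0.38. Drug metabolism genes fell by 0.36 (34 of 47, adjusted p = 0.000111; 2 adjusted over the list alone), with FMO5 at -0.95 ± 0.22. These 4 lists had an adjusted p of 0.626 with an estimated correlation, and each was called without every animal in turn and without 001 and 009 together. Leaving out a CR animal reaches the Control change only through the shared spread, scaling and filter, and tests little. Without animal 009, whose year 2 library stood apart, the medians were -0.26 (branched-chain), -0.15 (urea cycle) and -0.23 (drug metabolism), and without 006 drug metabolism stood at -0.20. Without both 001 and 009 the branched-chain median was -0.20. Spliceosome components (median 0.02, 53 higher and 44 lower, adjusted p = 0.625), splicing regulators (-0.03; 0.936), 3' end processing (-0.12; 0.249) and RNA decay (0.02; 0.833) were not called in Control.

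Further lists called lower in Control were hepatocyte secretory genes (-0.45, adjusted p = 4.88e-05), TCA cycle (-0.29), bile acids (-0.31), fatty acid oxidation (-0.21), insulin and IGF (-0.18), circadian clock (-0.33), acute phase (-0.34), unfolded protein response (-0.34), fatty acid synthesis (-0.22; 1 adjusted over the list alone) and proteasome (-0.13). Coagulation factor F9 (-0.93 ± 0.30) and antithrombin SERPINC1 (-0.79 ± 0.31) were among the secretory members of smallest p. Markers of other cells were called higher: endothelial (0.50, adjusted p = 0.000111; PLVAP 0.82 ± 0.25) and lymphocyte (0.40; 0.000223; LTB 1.65 ± 0.44, KLRB1 0.98 ± 0.28). Also higher were cholangiocyte (0.45; 0.00184; 3 adjusted over the list alone; TFF3 2.32 ± 0.59) and macrophage (0.38; 0.00435; SIGLEC1 0.90 ± 0.28, TYROBP 0.73 ± 0.27). The same held for stellate (0.38; 0.01; TIMP1 0.89 ± 0.22) and neutrophil (0.52; 0.0325; 2 adjusted over the list alone; MMP9 2.27 ± 0.44). The adjusted p of these 16 lists with an estimated correlation ran from 0.555 (circadian clock) to 0.806. In all 20 lists were called, 6 higher and 14 lower. Neither an estimated correlation nor fry gave a call (0 and 0), and 21 genes in the 40 lists passed when adjusted over the list alone.

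Many of these calls moved with the year 2 library of Control 009, in which albumin took 5.42% of the counts. Without animal 009 the hepatocyte secretory median was -0.082 (adjusted p = 0.0567), TCA cycle -0.12 (0.167), fatty acid oxidation -0.0050 (0.74), and insulin and IGF -0.058 (0.126). The median was 0.018 for the unfolded protein response (0.915), 0.10 for acute phase (0.548), 0.025 for the proteasome (0.787) and 0.038 for stellate markers (0.787). Without animal 006 the calls of macrophage (0.069), lymphocyte (0.20), neutrophil (-0.14), fatty acid oxidation (-0.12), fatty acid synthesis (-0.24) and proteasome (-0.091) genes were lost. The same held without 005 for macrophage (0.25), neutrophil (0.064), proteasome (-0.13), insulin (-0.14) and circadian (-0.51) genes. It held without 010 for stellate (0.28) and fatty acid synthesis (-0.17) genes, and without 001 for neutrophil markers (0.37). Without both 001 and 009, bile acid (-0.14), endothelial (0.21), cholangiocyte (0.26), stellate (0.037), fatty acid oxidation (-0.015), TCA cycle (-0.0074), insulin (-0.089) and unfolded protein response genes (-0.057) were not called. That setting brought calls of immediate-early genes (0.68, adjusted p = 0.000225), oxidative phosphorylation (-0.14; 0.000545) and the cytosolic ribosome (-0.13; 0.000476). Other leave-outs kept these calls and enlarged them. Without 001 the medians were -0.68 for secretory genes, -0.62 for acute phase, -0.52 for the unfolded protein response, -0.37 for fatty acid oxidation, -0.30 for insulin, -0.25 for the proteasome and 0.79 for lymphocyte markers. Without 009 macrophage markers stood at 0.60 and neutrophil markers at 1.20, and without both animals at 0.64 and 1.11. Fatty acid oxidation stood at -0.38 and stellate markers at 0.73 without 005, and without 010 fatty acid oxidation stood at -0.40, insulin at -0.38 and neutrophil markers at 0.92. Called but smaller were lymphocyte (0.25) and endothelial markers (0.28) without 009, and without both animals secretory (-0.29), acute phase (-0.12) and circadian genes (-0.069). With no animal block, fatty acid synthesis (adjusted p = 0.337), proteasome (0.0504) and neutrophil (0.0553) genes were not called, which left 17 lists. The hepatocyte secretory score changed by 0.51 in animal 001, -0.54 in 005, -0.30 in 006, -1.62 in 009 and -0.15 in 010.

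Single genes did not pass in the Control change either: edgeR called 0 of 13730, with 2005 at an unadjusted p under 0.05 (976 higher, 1029 lower; 686 by chance). With the spread of the Control libraries alone edgeR also called 0 genes. DESeq2 called 210 (114 higher, 96 lower) and limma on log2(TPM + 1) 0. Without animal 001 edgeR called 3 genes (2 higher, 1 lower). The genes of smallest p, which do not meet the rule, were LAT2, an adaptor of immune cell receptors (1.44 ± 0.24), AKR1B10, an aldose reductase relative (3.73 ± 0.64), BTNL9 (1.85 ± 0.34) and the ephrin receptor EPHB1 (3.26 ± 0.63). On the lower side were GNE, which starts sialic acid synthesis (-1.42 ± 0.21), THEMIS, a T cell gene (-1.64 ± 0.28), the fatty acid elongase ELOVL6 (-1.89 ± 0.35) and MYO5C (-0.83 ± 0.16). Their adjusted p ran from 0.231 to 0.289, and each had the same sign in 5 of 5 animals, as did 1293 genes (9.42%, against 6.25% by chance).

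The interaction, CR change minus Control change, tested whether the diets differed in their change. All list calls here are those of camera at its preset correlation, since an estimated correlation (adjusted p from 0.465 to 0.779) and fry gave 0. Cholesterol synthesis genes changed more upward in CR (adjusted p = 0.465 with an estimated correlation), with a median difference of 0.79 (24 of 27 higher, adjusted p = 3.3e-11; 1 adjusted over the list alone), HMGCS1 at 1.38 ± 0.33, MSMO1 at 1.27 ± 0.38 and DHCR7 at 1.64 ± 0.50 (SE, n = 5 per diet). Macrophage markers differed by -0.99 (24 of 25 lower, adjusted p = 1.8e-10), with SIGLEC1 at -1.31 ± 0.39 and lysozyme LYZ at -1.50 ± 0.56. Lymphocyte markers differed by -0.85 (28 of 28 lower, adjusted p = 1.13e-07), with CD247 at -1.65 ± 0.52 and GNLY at -1.65 ± 0.59. Endothelial markers differed by -0.68 (24 of 26, adjusted p = 1.13e-07), with PLVAP at -1.13 ± 0.36 and STAB2 at -1.10 ± 0.36. These 4 lists had an adjusted p of 0.465 with an estimated correlation. Hepatocyte secretory genes differed by 0.51 (33 of 34 higher, adjusted p = 1.3e-07, adjusted p = 0.504 with an estimated correlation), with HRG, a plasma glycoprotein, at 1.59 ± 0.40. Urea cycle genes differed by 0.47 (adjusted p = 8.23e-06) and drug metabolism by 0.41 (0.000115), with the sulfotransferase SULT2A1 at 1.44 ± 0.39, both with an adjusted p of 0.465 with an estimated correlation. Oxidative phosphorylation (0.21, adjusted p = 5.02e-05), mitochondrial ribosome (0.25; 5.4e-05) and proteasome (0.27; 7.27e-05) genes had an adjusted p of 0.56 with an estimated correlation. These 10 lists were called without each animal in turn and without 001 and 009 together. CR minus Control of the oxidative phosphorylation score was -0.26 at year 0 and -0.03 at year 2. For the mitochondrial ribosome it was -0.22 and 0.01, so that both interactions lay almost wholly in the year 0 difference. The cholesterol score was at -0.39 and 0.38, and that of the proteasome at -0.18 and 0.08.

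Spliceosome components differed between the diets' changes by 0.12 in median (60 of 97 higher, adjusted p = 0.0352, adjusted p = 0.56 with an estimated correlation), with SF3B14 at 0.61 ± 0.22, MAGOHB at 0.69 ± 0.26 and PRPF18 at 0.58 ± 0.22. This call was lost without animal 004 (0.082), 005 (0.016), 006 (0.080), 010 (0.11) or 012 (0.053), while without 001 and 009 together the median was 0.19 (adjusted p = 2.92e-05). The spliceosome score changed by 0.14 ± 0.11 in CR and 0.05 ± 0.22 in Control (SD, n = 5), a difference of 0.09 (exact p = 0.444). CR minus Control of this score was -0.17 at year 0 and -0.08 at year 2, so that CR stood lower at both times. Splicing regulators (0.10, adjusted p = 0.0512), 3' end processing (0.17, 0.0779) and RNA decay (0.07, 0.465) were not called in the interaction. With no animal block the splicing regulators were called, at a median of 0.084 (adjusted p = 0.040), and without 001 and 009 together at 0.15 (adjusted p = 0.0092).

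Other lists with a positive interaction were branched-chain amino acids (0.48), bile acids (0.40), circadian clock (0.37, with the clock output gene HLF at 1.08 ± 0.33 and CRY2 at 1.03 ± 0.39), insulin and IGF (0.37), and acute phase (0.36). Smaller ones were those of the unfolded protein response (0.34), fatty acid oxidation (0.33), TCA cycle (0.30), heat shock (0.26), fatty acid synthesis (0.22; 1 adjusted over the list alone) and cytosolic ribosome (0.15). Negative were interferon (-0.49) and neutrophil genes (-0.73; 3 adjusted over the list alone; MNDA -2.38 ± 0.63). Adjusted p of these 13 lists ran from 1.04e-05 to 0.0429, and with an estimated correlation from 0.465 to 0.779. In all 24 lists were called, 19 higher and 5 lower. With an estimated correlation 0 were called and by fry 0, and 7 members in the 40 lists passed when adjusted over the list alone. Without animal 009 the calls of fatty acid oxidation (0.018), TCA cycle (0.084), insulin (0.16), unfolded protein response (0.018), heat shock (0.091), acute phase (-0.015) and fatty acid synthesis (0.20) were lost. Without both 001 and 009 the calls of bile acids (0.098), branched-chain amino acids (0.13), circadian clock (0.23, adjusted p = 0.0744), fatty acid oxidation (0.054), TCA cycle (0.071), insulin (0.13), unfolded protein response (0.12), heat shock (0.015) and fatty acid synthesis (0.29) were lost. That of interferon was lost without 004 (-0.17). Cytosolic ribosome was lost without 004 (0.083), 005 (-0.091), 006 (0.075) or 012 (0.11), and neutrophil markers without 004 (-0.29), 005 (-0.15) or 006 (-0.068). The same held for the circadian clock without 001 (0.42) or 005 (0.36). Heat shock was also lost without 004 (0.23), 006 (0.13), 011 (0.18) or 012 (0.28). Fatty acid synthesis was also lost without 004 (0.15), 006 (0.14), 007 (0.058), 010 (0.12) or the animal block (adjusted p = 0.358). Without both 001 and 009 the calls of neutrophil markers (-1.61, adjusted p = 8.62e-06) and of the cytosolic ribosome (0.40; 1.26e-12) were kept and larger, and that of acute phase was smaller (0.16). Calls also kept and larger were neutrophil without 009 (-1.50), cytosolic ribosome without 001 (0.31) or 010 (0.24), and unfolded protein response (0.60) and acute phase (0.61) without 001. The same held for fatty acid oxidation (0.51) and heat shock (0.44) without 005 and interferon without 011 (-0.75). Kept and smaller were bile acids (0.20) and branched-chain amino acids (0.27) without 009, circadian clock without 006 (0.23) and neutrophil markers without 007 (-0.42). Among the 10 lists kept, leaving out 009 moved hepatocyte secretory genes to 0.23, urea cycle to 0.25, drug metabolism to 0.23, proteasome to 0.11, mitochondrial ribosome to 0.11 and oxidative phosphorylation to 0.086. Without 001 the mitochondrial ribosome and oxidative phosphorylation stood at 0.41 each, and without 006 oxidative phosphorylation stood at 0.13 and lymphocyte markers at -0.56. Drug metabolism stood at 0.26 without 005, and lymphocyte markers at -0.47 without 004. Without both 001 and 009 endothelial markers stood at -0.31 and drug metabolism at 0.24. The interaction and the CR change use the year 0 libraries that also differed between the arms. Both mirror part of the year 0 difference by construction, and some interactions lay almost wholly in it.

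**Figure D3:**
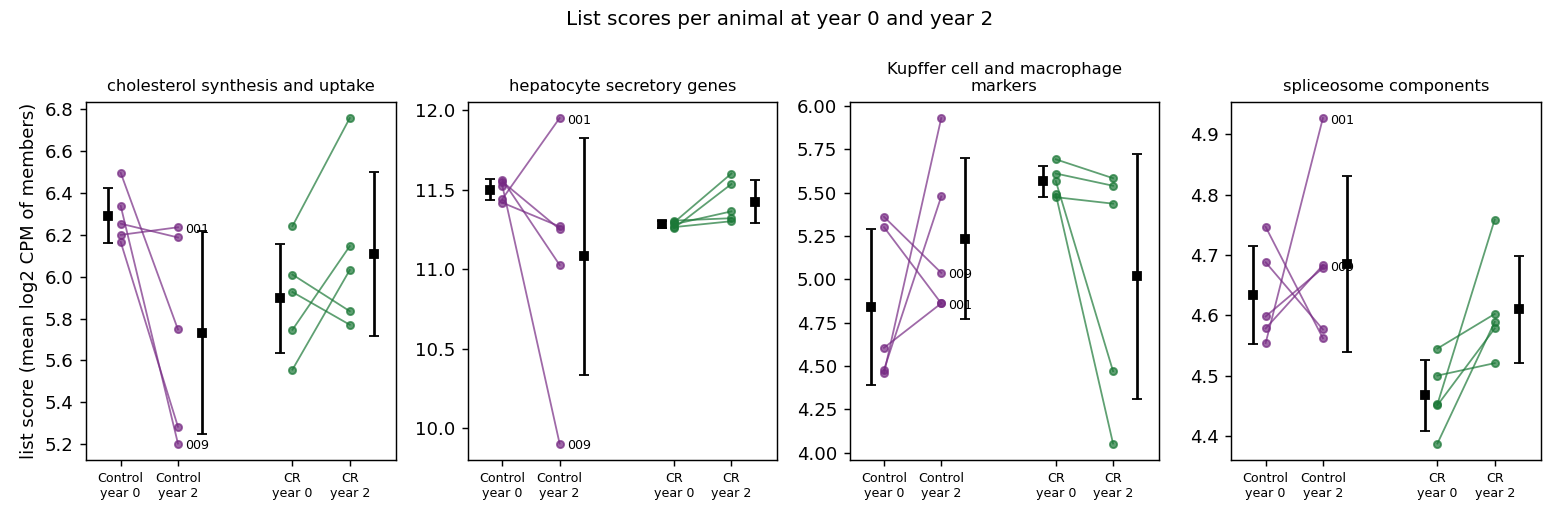
Mean log2 CPM of list genes (vertical axis) at year 0 and year 2 for each animal (lines) of both diets, with squares for the mean ± SD of 5 animals and labels for animals 001 and 009. The macrophage score in CR went from 5.57 ± 0.09 to 5.02 ± 0.71.

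On exact tests of the scores, cholesterol synthesis genes changed by 0.21 ± 0.35 in CR (higher in 3 of 5) and by -0.56 ± 0.52 in Control (higher in 1 of 5), a difference of 0.77 (SD, n = 5 per diet; exact p = 0.0476, adjusted over the lists 0.451). Macrophage scores differed by -0.94 (exact p = 0.111), since they changed by -0.55 ± 0.67 in CR (lower in 5 of 5) and 0.39 ± 0.83 in Control (higher in 3 of 5). Hepatocyte secretory scores changed by 0.14 ± 0.14 in CR (higher in 5 of 5) and -0.42 ± 0.78 in Control (higher in 1 of 5), a difference of 0.56 (exact p = 0.135). The smallest exact p of an interaction was that of 3' end processing (a difference of 0.16; exact p = 0.0159, adjusted over the lists 0.451). Cholangiocyte scores changed by 0.61 ± 0.63 in CR (5 of 5 higher) and 0.57 ± 0.54 in Control (4 of 5 higher), with an exact p of 0.937 for the difference of 0.04. The CR value leans on animal 004, without which the list median in CR was 0.21 instead of 0.43, and without 001 and 009 that in Control was 0.26 and not called. At year 0 macrophage (0.73), spliceosome (-0.17), oxidative phosphorylation (-0.26) and hepatocyte secretory (-0.22) scores differed between the arms with the smallest exact p that 5 against 5 allow (0.00794, adjusted over the lists 0.0542). No score passed after adjustment in any comparison.

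For single genes edgeR called 0 of 13730 in the interaction, with 941 at an unadjusted p under 0.05 (363 higher, 578 lower; 686 by chance). DESeq2 called 41 (16 higher, 25 lower) and limma on log2(TPM + 1) 0. Without animal 001 edgeR called 1 gene, lower in CR. The genes of smallest p, which do not meet the rule, were THEMIS (2.36 ± 0.39), SLAIN1 (2.19 ± 0.44), ELOVL6 (2.42 ± 0.50) and IRX3 (3.05 ± 0.66) on the higher side. On the lower side were LAT2 (-1.77 ± 0.34), MRC2 (-1.53 ± 0.30), PILRA (-2.11 ± 0.43) and the autophagy receptor OPTN (-1.05 ± 0.21), with adjusted p from 0.581 to 0.625. The values of CR and Control did not overlap in 241 genes (1.76%, against 0.794% by chance). Of the panel, PDK4, which restrains glucose oxidation, stood at 0.94 ± 0.40 with an adjusted p of 0.720. FASN (1.08 ± 0.74), IGF1 (0.81 ± 0.43), G6PC (0.96 ± 0.62), ACACA (0.65 ± 0.36), SIRT1 (0.47 ± 0.36), SRSF1 (0.34 ± 0.30), HNRNPA1 (0.27 ± 0.25) and SREBF1 (-0.10 ± 0.60) were not called.

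At year 2 the diets were compared on treatment, in different animals, and 0 lists were called with an estimated correlation or by fry. Red blood cell markers were lower in CR in 8 of 8 genes, with a median of -1.44 (adjusted p = 8.3e-05, adjusted p = 0.917 with an estimated correlation), among them the anion exchanger gene SLC4A1 (-1.89 ± 0.68, SE, n = 5 per group) and carbonic anhydrase CA1 (-1.72 ± 0.59). This list was called without each animal in turn, with a median of -0.77 without 001 and -0.55 without 001 and 009, and it was also lower in CR at year 0 (-0.98). Cholesterol synthesis genes were higher in CR by 0.32 (20 of 27, adjusted p = 0.000384). Branched-chain amino acid genes (0.29, adjusted p = 0.000384; PPM1K 1.08 ± 0.39), cell cycle genes (0.45; 0.00113), hepatocyte secretory genes (0.21; 0.00113; HRG 0.92 ± 0.33), drug metabolism (0.11; 0.00805) and bile acids (0.17; 0.0155) were higher. Endothelial (-0.46; 0.00195; VWF -0.60 ± 0.21, CLEC4G -1.25 ± 0.45), lymphocyte (-0.34; 0.00805) and stellate markers (-0.52; 0.00941; TIMP1 -0.87 ± 0.28) were lower. These 10 lists had an adjusted p of 0.917 with an estimated correlation, fry called 0, and 0 genes passed when adjusted over the list alone. Spliceosome components (-0.13, adjusted p = 0.335), splicing regulators (-0.02; 0.805) and macrophage markers (-0.20; 0.14) were not called at year 2. The median log2 change of all tested genes at year 2 was -0.067, so that list medians at year 2 include this shared shift. Without 001 and 009 macrophage (-0.37, adjusted p = 0.000648), neutrophil (-0.53; 0.034) and immediate-early genes (-0.36; 0.00314) were called lower in CR and cholangiocyte markers higher (0.44; 0.00109).

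Without animal 009 the year 2 medians were -0.062 for hepatocyte secretory genes (adjusted p = 0.333), -0.21 for endothelial markers (0.121), and -0.15 for stellate markers (0.637). They were -0.049 for lymphocyte markers (0.328), 0.088 for branched-chain amino acids (0.0604), 0.14 for drug metabolism (0.119) and 0.22 for bile acids (0.0611). Without animal 004 the calls of cholesterol (0.24; 0.0796), endothelial (-0.34), lymphocyte (-0.22) and drug metabolism genes (0.14) were lost. Cell cycle was lost without 007 (0.19) or 008 (0.25), bile acids without 007 (0.12) and drug metabolism without 005 (0.075). The same held for lymphocyte markers without 006 (-0.27) and stellate markers without 010 (-0.50). Without 001 and 009 together the calls of bile acids (0.090), branched-chain amino acids (0.067), stellate (-0.22), lymphocyte (-0.12) and endothelial markers (-0.085) were lost. Called and larger were cholesterol genes without 010 (0.53), bile acids without 005 (0.26), lymphocyte markers without 001 (-0.53) or 011 (-0.52), secretory genes without 001 (0.47), and drug metabolism without 001 (0.24) or without 001 and 009 (0.17). At year 2 edgeR called 0 of 13345 genes, with 938 at an unadjusted p under 0.05 (153 higher, 785 lower; 667 by chance). DESeq2 called 7 (1 higher, 6 lower) and limma on log2(TPM + 1) 0. The smallest p, none meeting the rule, belonged to MMP10 (3.84 ± 0.97), TMED6 (1.38 ± 0.36), SLAIN1 (1.22 ± 0.32) and ZNF846 (1.14 ± 0.30). On the lower side it belonged to CEP57L1 (-2.00 ± 0.43), MLPH (-0.99 ± 0.22), LRRC4B (-1.87 ± 0.43) and AATK (-1.27 ± 0.30), each with an adjusted p of 0.659. The 5 values of each diet did not overlap in 102 genes (0.764%, against 0.794% by chance).

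Transcript usage addressed RNA processing, which the title of the series names. In Control, 3 of 1185 genes were called for transcript usage over 2 years: SLC9A7, a sodium-proton exchanger of the Golgi (adjusted p = 0.00346), COL18A1, the gene of collagen XVIII (adjusted p = 0.00346), and MYO1C, an unconventional myosin (adjusted p = 0.00533). Chance was not excluded for these 3 calls, as given below, and 0 genes were called without animal 009. The second COL18A1 transcript made up 74.1% of the gene's RNA in Control 009 and 23.5% in Control 001 at year 2, against 4.86% in 010, 1.36% in 006 and 0.678% in 005, and at most 1.62% in every library of the other 3 groups. The first SLC9A7 transcript was listed at 0 in 5 of 5 Control libraries at year 0 and made up 85.0% in 001, 79.8% in 005, 85.4% in 009 and 79.1% in 010 at year 2, with 0 in 006. In CR it made up 79.2% in animal 007 at year 0 and was listed at 0 in the other 9 libraries, and the gene was at 0.66 to 2.13 TPM. The first MYO1C transcript made up between 7.37% and 39.5% in Control at year 0, and at year 2 5.58% in 001 and 0 in the other 4. In CR it ranged from 5.07% to 42.7% at year 0 and from 12.0% to 30.1% at year 2.

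In CR, diffSpliceDGE called 0 genes for transcript usage, with 24 at an unadjusted p under 0.05 and a smallest adjusted p of 0.557, and voom with diffSplice called 0. The interaction called COL18A1 (adjusted p = 0.0147) and GTDC1 (adjusted p = 0.0152), while SLC9A7 (0.0526) and MYO1C (0.0566) did not pass. The first GTDC1 transcript was listed at 0 in 5 of 5 Control libraries at year 0 and made up 23.4% in 006, 59.3% in 010 and 78.1% in 009 at year 2, with 0 in 001 and 005. In CR it made up 24.0% in 004, 33.5% in 007, 32.2% in 008, 0 in 011 and 35.9% in 012 at year 0, and was listed at 0 in 5 of 5 libraries at year 2. Between the diets at year 2 diffSpliceDGE called 0 genes, with 53 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0626, and voom with diffSplice called 0. Without animal 009, whose year 2 library stood apart, 0 genes were called in Control and 0 in the interaction, and without 005 the calls were 3 in CR, 11 in Control, 4 in the interaction and 7 at year 2. With no animal block 5 genes were called in Control and 3 in the interaction, while SLC9A7 (adjusted p = 0.0739) and MYO1C (0.0692) were lost in Control and COL18A1 (0.0648) in the interaction. An estimate at exactly 0 for a transcript may come from how reads were divided between transcripts and is given here only as listed.

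**Figure D4:**
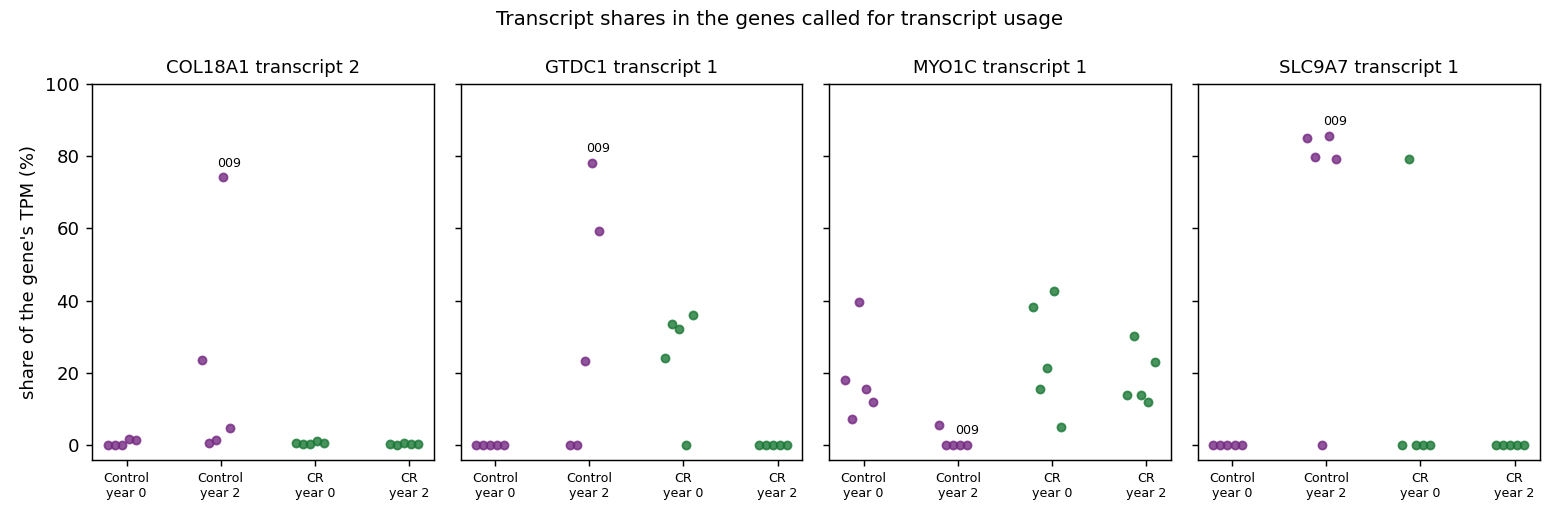
Share of the gene's RNA in percent (vertical axis) given by 1 transcript each of COL18A1, GTDC1, MYO1C and SLC9A7, with 1 point per library in the 4 groups. The COL18A1 transcript stands at 74.1% in Control 009 and 23.5% in Control 001 at year 2.

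The changes of the diets were compared across genes. Across 13730 genes, which are not independent replicates, the log2 changes of CR and Control had a Pearson r of 0.145 and a Spearman rho of 0.175. Of the 126 ways to divide the 10 animals into 5 and 5, 19 gave an r as low as this (permutation p = 0.151, one-sided), with a median of 0.269. Without animal 001 r was 0.014, without 012 0.063 and without 004 0.095, and without 001 and 009 together it was -0.116 (permutation p = 0.0893).

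The authors deposited log2 fold changes and p-values of a comparison that the file does not name. By the authors' deposited values, 514 genes had an adjusted p under 0.05, 118 higher and 396 lower, and this adjusted p equals a Benjamini-Hochberg adjustment over the genes listed there. The deposited log2 fold changes correlated across genes with those of DESeq2 for the interaction at a Pearson r of 0.9997 and a Spearman rho of 0.999, with 92.4% of signs shared and a median offset of 0.11 (own minus authors). This offset was nearly the same across genes, with quartiles of 0.112 and 0.114. With the CR change of DESeq2 the Pearson r was 0.784 and with its Control change -0.894. For the same interaction DESeq2, fitted with the animal block, called 42 genes over all genes of the deposited counts. It called 106 when adjusted over the genes the authors listed.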

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

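The tests of explanations in this part were chosen after the results were seen, while the regrouping of samples was planned before. A single value stood far from the other 4 of its group in 14 of 236 groups checked, against 11.8 by chance, since about 1 in 20 groups stands out with no cause. By kind these were 1 of 32 groups of library measures, 10 of 164 of list scores, 3 of 16 of transcript shares and 0 of 24 of CPM values at year 0.

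Control animal 009 at year 2 held 6 of the 14. Relative to the mean over 20 libraries its scores were -0.67 for ketone bodies (the other 4 from -0.01 to 0.20), -0.58 for gluconeogenesis (-0.09 to 0.08), -1.08 for branched-chain amino acids (-0.28 to 0.03), -0.73 for one-carbon metabolism (-0.10 to 0.16), -0.43 for NRF2 (0.06 to 0.17) and -1.11 for the unfolded protein response (-0.04 to 0.14). CR animal 004 had albumin at 11.0% of counts at year 0 (the other 4 from 14.3% to 15.6%), a mitochondrial ribosome score of -0.22 at year 0 (-0.14 to -0.12) and a cholangiocyte score of 1.41 at year 2 (-0.19 to 0.22). At year 2 CR animal 012 had a circadian clock score of -0.32 (0.02 to 0.15) and CR animal 011 an unfolded protein response score of 0.28 (-0.02 to 0.01). The MYO1C transcript stood at 5.58% in Control 001 at year 2 (0 in the other 4). The SLC9A7 transcript stood at 0% in Control 006 at year 2 (79.1% to 85.4%) and at 79.2% in CR 007 at year 0 (0 in the other 4).

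The diets differed in their change over 2 years in 24 lists by camera at its preset correlation, in 0 with an estimated correlation (adjusted p from 0.465 to 0.779) and in 0 by fry. The median differences were 0.79 for cholesterol synthesis, 0.51 for hepatocyte secretory genes, 0.48 for branched-chain amino acids, 0.47 for the urea cycle, 0.41 for drug metabolism, 0.40 for bile acids, 0.37 for insulin and IGF, 0.37 for the circadian clock, 0.36 for acute phase, 0.34 for the unfolded protein response, 0.33 for fatty acid oxidation and 0.30 for the TCA cycle. Smaller ones were 0.27 for the proteasome, 0.26 for heat shock, 0.25 for the mitochondrial ribosome, 0.22 for fatty acid synthesis, 0.21 for oxidative phosphorylation, 0.15 for the cytosolic ribosome and 0.12 for the spliceosome. Negative were macrophage (-0.99), lymphocyte (-0.85), neutrophil (-0.73), endothelial (-0.68) and interferon genes (-0.49). In transcript usage COL18A1 (adjusted p = 0.0147) and GTDC1 (adjusted p = 0.0152) were called.

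Macrophage markers fell in CR relative to Control by 0.99 in median by camera at its preset correlation. With an estimated correlation (adjusted p = 0.465) and by fry the list was not called, and the score's exact p was 0.111. The difference between the arms at enrolment made up 77.0% of the interaction of the macrophage score, which leaves a start apart open as part of the cause. At year 2 macrophage markers were lower in CR by 0.20 in median and not called, and without 001 and 009 by 0.37 (adjusted p = 0.000648 at the preset correlation). The year 2 libraries of 001 and 009 are no likely cause, since the median was -1.21 without both animals. A different share of hepatocytes in the biopsies could neither be kept nor excluded: the macrophage score minus the cholangiocyte score changed by -1.16 in CR and -0.17 in Control (interaction -0.99, exact p = 0.254, n = 5 per diet). Such a share would move both scores alike, and their interactions were -0.94 (macrophage) and 0.04 (cholangiocyte). These were unlike, but not beyond the spread between animals. The cholangiocyte score in CR also leaned on animal 004. Relative to the mean over 20 libraries it stood at 1.41 there at year 2 (the other 4 from -0.19 to 0.22). Cell counts in sections of the same biopsies would separate fewer macrophages from less RNA per macrophage.

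Hepatocyte lists fell in Control over 2 years. Without both 001 and 009 the median was -0.29 for secretory genes and -0.44 for cholesterol genes, and both lists were still called at camera's preset correlation. With an estimated correlation or fry 0 lists were called in Control in the fit of all animals. A fall was thus also seen in the animals other than 001 and 009. For secretory genes this cannot exclude the library of 009 as the main cause, since animal 001 changed the other way (0.51) and was left out with it. Without 009 alone the secretory genes stood at -0.082 and were not called. A lower share of hepatocytes in the biopsies would raise the markers of all other cell types, and the mean change was above 0 in 6 of 6 marker scores, from 0.36 ± 0.78 (stellate) to 0.57 ± 0.54 (cholangiocyte; SD, n = 5). This fits a lower share, though the SD between animals was close to the mean or larger. In animal 006, with a secretory change of -0.30, all 6 marker scores were higher, and in 010 (-0.15) 4 were higher and 2 lower. Against it, animal 005 had a secretory change of -0.54 with 4 of 6 marker scores lower, while macrophage (1.00) and neutrophil (1.53) scores were higher. Also against it, animal 001 had a secretory change of 0.51 with 5 of 6 marker scores higher, among them neutrophil (0.95), cholangiocyte (0.92) and endothelial (0.76). In animal 009 the stellate (1.58), endothelial (1.31), lymphocyte (1.29) and cholangiocyte (1.21) scores were higher while macrophage (-0.32) and neutrophil (-1.75) scores were lower. A lower share of hepatocytes thus stays open as a cause, also in 009, where the secretory score changed by -1.62.

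Transcript usage calls in Control were 3 in the fit of all animals, 0 without animal 009 and 4 in median when another animal was left out. Without 009 the adjusted p was 0.0532 for SLC9A7, 0.0532 for COL18A1 and 0.136 for MYO1C, while without 001 and 009 together MYO1C was the 1 gene called. The mean change in share of the SLC9A7 transcript was 65.9 ± 36.9 points with all 5 animals and 61.0 ± 40.7 without 009 (SD), 92.6% of its size. For MYO1C it was -17.4 ± 12.7 and -17.9 ± 14.6 (103%), so that the library of animal 009 at year 2 is not the whole cause of either change, and the calls ended with 4 animals at a like size. The COL18A1 change went from 20.2 ± 30.7 to 7.17 ± 10.9 points (35.4%), which fits a call that leans on the library of 009. The shares in Control 001 and 010 at year 2 were also above those of every library of the other groups. The change was thus not confined to 009. The year 2 library of 009 had the fewest counts (15421789) but the most genes detected (15596). Chance was not excluded for the 3 calls, since 6 of the 16 groupings that part the biopsies of all 5 animals, the real one included, called at least 3 genes. Transcript-specific PCR of COL18A1 in the same RNA could tell a change of the liver from one of that library.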

How the results depend on the processing

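Only the tests without animals 001 and 009 together were chosen after the results were seen. With the shallowest library at 15421789 counts and 5 animals per diet, a 2-fold change was recovered for 28.4% of simulated genes in the CR change and for 1.49% in the interaction, so that counts of 0 genes do not exclude changes of that size. Where a value moved, the cause was not tested.

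Camera's list counts were 0 with an estimated correlation in each of the 5 comparisons, and fry gave 0 in the CR change, Control change, interaction and year 2 comparison and 9 at year 0. DESeq2 called 18 genes in the CR change, 210 in the Control change, 41 in the interaction, 7 at year 2 and 780 at year 0, where edgeR called 0, 0, 0, 0 and 32. At year 0 limma on log2(TPM + 1) called 361, edgeR without a filter 13 and edgeR with all 20 libraries 0. Without animals 001 and 009 the gene counts were 1, 1, 1, 2 and 228 in the same order, and transcript usage called 1 gene in Control and 1 at year 2. With no animal block transcript usage called 5 genes in Control instead of 3. The lack of the block also ended the calls of fatty acid synthesis, proteasome and neutrophil genes in Control and of fatty acid synthesis in the interaction. It brought a call of splicing regulators in the interaction (0.084), and it ended the transcript usage calls of SLC9A7 and MYO1C in Control and COL18A1 in the interaction. Leaving out the block changed no other call of a list or named gene. For transcript usage voom with diffSplice called 8 genes in Control, the gene-level F test 2 at year 2, and a share of at least 10% gave 1 in CR.

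Leaving out 1 animal at a time, genes called ran from 0 to 1 in the CR change, 0 to 3 in the Control change, 0 to 1 in the interaction, 0 to 0 at year 2 and 3 to 340 at year 0. Lists called ran from 14 to 20, 13 to 24, 18 to 27, 7 to 18 and 17 to 24 in the same order. Transcript usage calls ran from 0 to 3 in CR, 0 to 11 in Control, 0 to 4 in the interaction and 0 to 7 at year 2. The correlation of the diets' changes ran from 0.014 to 0.219.

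The list values here are medians, given where 1 animal was left out with the other end of the range over left-out animals. Directions of the list test were turned in 8 list values called in at least 1 of the 2 fits. Without 001 and 009 these were the TCA cycle in Control (-0.0074) and in the interaction (0.071) and the cytosolic ribosome in Control (-0.13). Without 004 they were interferon (-0.025, against -0.54 without 011) and lymphocyte genes (-0.0039, against -0.44 without 011) in CR, and without 005 the cytosolic ribosome in the interaction (-0.091, against 0.31 without 001). Without 009 they were acute phase genes in Control (0.10, against -0.62 without 001) and the mitochondrial ribosome at year 2 (-0.20, against 0.12 without 001). Medians of other called lists also changed sign, such as the unfolded protein response in Control and secretory genes at year 2, both without 009. Of the other list values 292 were weaker, 105 stronger and 2315 the same, and of the named gene values 110, 156 and 5599, with 0 turned among those called in either fit. Apart from the 8, 130 of 2720 list values changed direction in the list test and 65 of 5865 named gene values changed sign, without a call in either fit. Of the transcript usage values 16 were weaker and 57 the same.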

Other observations

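The transcripts in this part were picked after their values were seen, while the tests by regrouping were planned before. HMOX2, which encodes the constitutive heme oxygenase, showed 1 transcript that was either near absent or at about 700 counts. The third HMOX2 transcript made up 60.8% of the gene's RNA in Control 005 (701 counts) and 51.1% in Control 010 (701 counts) at year 0, and 55.4% in Control 006 (700 counts) at year 2. In CR at year 0 it made up 53.8% in 007 (700 counts), 40.2% in 008 (708 counts) and 62.6% in 011 (686 counts). In the other 14 libraries it had between 0 and 3 counts, and no animal had it at both times. The near-equal counts at differing gene levels point to how reads were divided between transcripts, but this was not tested.

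In the year 2 library of Control 009 2 further genes were listed with a transcript at its highest share of the 20 libraries. The first transcript of GCLC, the catalytic subunit for glutathione synthesis, made up 66.2% in Control 009, 40.1% in 001 and 11.3% in 010 at year 2, and at most 2.59% in each of the other 17 libraries. The third transcript of FASTK made up 44.7% in Control 009, 32.5% in 001 and 12.3% in 010 at year 2, and 15.5% in Control 005 at year 0.

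Hepatocyte secretory scores were close to each other in CR, at 11.283 ± 0.020 at year 0 and 11.426 ± 0.14 at year 2, and spread more in Control at year 2, at 11.081 ± 0.74 (SD, n = 5). The animal of the lowest change was 009 (-1.62).

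Regrouping the 10 libraries or animals of a comparison in 100 of the 126 possible ways, the real one included, tests a count only where the real grouping called a gene. With 0 genes called all 100 groupings have at least as many, which tests nothing: this held for genes in the CR change (at most 0 in another grouping), Control change (2886), interaction (2) and year 2 comparison (1), and for transcript usage in the CR change (1) and at year 2 (33). At year 0 2 groupings reached the real count (32 genes, at most 302). For transcript usage 20 did in the Control change (3, at most 55) and 16 in the interaction (2, at most 8), so that chance was not excluded for these calls. In Control most groupings part fewer than 5 pairs, and of the 16 that part all 5, the real one included, 6 called at least 3 genes. The highest count in Control came from groupings that parted only the biopsies of animal 009, while the 15 others that parted all 5 pairs called at most 0 genes and at most 38 in transcript usage. At year 0 the grouping with 302 genes put animals 001, 004, 010, 011 and 012 against the rest, which points to a structure of the samples other than diet, or to the highest of many groupings, and this was not tested. Only 2 of 100 groupings, the real one included, reached 32 genes, which a difference between the arms at enrolment could give. The count ran from 3 to 340 when 1 animal was left out, and no score passed after adjustment. A difference between the arms thus stays open and is not established.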
